A study of Mus musculus with 6 samples.

How the data were processed

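The data are expression values of 6 mouse gonad samples (ovary and testis at 3 ages), 1 array each, with biotin-labelled RNA prepared from total RNA, per the labels' protocols. How many animals gave RNA to each sample is not given in the sources used here. The deposited table holds 1 intensity value for each of 45101 probe sets and array on a linear scale. GCOS version 1 is named in the submitters' processing notes, without its role. The background correction, the summary of probes into probe sets and any scaling between arrays are not given in the sources used here. The values themselves show a lowest value of 1, which between 277 and 586 probe sets per array hold, and 2% trimmed means between 256 and 353, so the arrays do not share a common trimmed mean. Which part of an array's brightness is background therefore stays unknown, and ratios of dim genes are compressed or inflated by an unknown amount.

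Each array was multiplied by 1 factor to the same 2% trimmed mean, with factors between 0.913 and 1.26. A common floor was set at the median of all scaled signals, 75.3, and lower values were raised to it. Ratios were taken after this step. When 1 of the arrays was at the floor the ratio is a lower bound, written as at least N-fold, and values at the floor have no order. List medians are taken over the floored values, so a median that rests on a gene at the floor is a bound too. The platform annotation named 35890 probe sets, 34945 with 1 gene symbol, 932 with several and 13 controls, and left 9211 unnamed. Only probe sets with 1 symbol were used, and each gene was represented by its probe set with the highest mean signal, which gave 18193 genes, of which 9010 had 2 or more probe sets. Of these symbols 18032 were found in the reference gene table of assembly GRCm38.p6, which was used for names and chromosomes and for no coordinates. All 64 control probe sets were left out of the genes and used as checks of RNA integrity and hybridization.

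A gene was called higher or lower at a ratio of 4 or more. The results are counts of called genes, medians of gene lists and the overlap of 2 comparisons, and none has a test, because each group has 1 array. The 7 comparisons were ovary against testis at each age, adult against neonatal testis, neonatal against fetal testis, and neonatal against fetal and adult against neonatal ovary. The overlap was set beside the number that independent lists of the same sizes would share. For each gene list, the median log2 ratio of the members above the floor on at least 1 array was placed among 10000 random lists of the same size, drawn within 20 bins of mean log2 signal. The spread used to judge a log2 ratio is its robust SD. For it, the difference between 2 probe sets of a gene, both above the floor on both arrays, was divided by the square root of 2. This SD is technical and covers no variation between animals or arrays.

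Before the data were examined, 32 gene lists with 410 genes were fixed, together with the comparisons, the limit of 4, the floor, the alternatives and the rule for naming genes. Of the list genes, 360 were matched to a gene on the arrays, and the others, such as Lhcgr, Insl3, Cyp19a1 and Gapdh as a gene, are not analysed here. The lists were meiotic cohesins, synaptonemal complex and axis, meiotic recombination, telomere attachment, meiotic entry, meiosis I segregation and kinetochore, mitotic cohesins, proliferation, germ cells of both sexes, pluripotency, fetal male germ cell, spermatogonia, late spermatocyte, spermatid, oocyte, granulosa, corpus luteum and theca, Sertoli, Leydig, blood, macrophage, endothelium, smooth muscle, duct and oviduct epithelium, adrenal cortex, Y-linked genes, imprinted growth genes, autosomal retrocopies, their X-linked parents, housekeeping, oxidative phosphorylation and extracellular matrix. Named genes are, per comparison and direction, the 6 with the largest ratio among genes above the floor on both arrays and the 6 brightest among genes at the floor on the other array, the members of the overlap (up to 20), and members of the lists.

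Alternatives were quantile normalization, signals as deposited, scaling to the same median, floors at the 25th and 75th percentile, no floor with 16 added, the mean of all probe sets of a gene, and omission of probe sets that can cross-hybridize. For the overlap, ratios of 2 and 8 and the fetal testis as reference were added. Scaling to 9 hybridization controls, RNAs added in a fixed amount before hybridization, was chosen after the data were seen, because their mean signal differed between the arrays.

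The steps were tested on simulated arrays made from the fetal testis values with a noise SD set to 0.2 (log2) per array. In them 200 of 18193 genes, all above 4 times the floor in fetal testis, were raised in fetal ovary over fetal testis. All 50 genes raised 8-fold and all 50 raised 16-fold were called, 23 of 50 raised 4-fold, and none of 50 raised 2-fold, and 0 of 17993 unchanged genes were called. Raised genes near the floor were not simulated, and the 0 false calls hold for this noise only. In the comparisons with adult testis the SD of 1 log2 ratio from pairs of probe sets was 0.57 and 0.63. Of 200 random lists, 4.5% lay outside the central 95% of the percentiles. These lists were drawn at random from genes with independent noise, so this share checks the calculation only. It does not cover lists of genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.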

Results

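Gonads of C57BL/6 mice, an inbred laboratory strain, were compared on 6 Affymetrix arrays that each measured 45101 probe sets. Ovary and testis were each sampled at 15.5 days postcoitum (fetal), on postnatal day 1 (neonatal) and at 10 weeks after birth (adult), with 1 array per group. There were therefore no replicates, no difference has a replicate check, and no p-value or standard error was computed. Genes are described by a fixed size, a ratio of 4 or more between 2 arrays, and the number of arrays limits the precision. The contrast in meiosis lies between fetal ovary and fetal testis and between adult and neonatal testis. Germ cells of the fetal ovary are in meiotic prophase at 15.5 days postcoitum. Those of the fetal and neonatal testis have not entered it, and the adult testis holds spermatocytes and spermatids. Neonatal and adult ovary are not references without meiosis. In neonatal ovary the meiotic genes Sycp3 and Smc1b still had signals of 3051 and 1068. The series was presented as a screen for genes that act when chromosomes separate in the first meiotic division.

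The median deposited signal per array lay between 64.1 in neonatal ovary and 82.5 in fetal ovary. After scaling, signals under a floor of 75.3 were set to it, and between 11906 (neonatal testis) and 12661 (neonatal ovary) of 18193 genes lay above it. The sex of each array was visible in its values. Eif2s3y, a Y-linked translation factor gene, was at the floor in the 3 ovaries and had signals of 1065, 1091 and 757 in fetal, neonatal and adult testis. Xist, the RNA that silences 1 X chromosome in female cells, had signals of 4085, 1950 and 3049 in the ovaries and of at most 139.6 in the testes. Across 15282 genes, which are not independent replicates, log2 signals of fetal ovary and fetal testis correlated with r = 0.969, and those of adult testis correlated with the other 5 arrays with r between 0.384 and 0.425. The ratio of 3' to 5' signal, a measure of RNA integrity, was taken from 2 control genes that ordered the arrays differently. For Gapdh it was 3.12 in neonatal ovary and 2.36 in adult testis, against 1.32 to 1.45 on the other 4 arrays. For Actb it was highest in fetal ovary (3.78), 3.28 in neonatal ovary and lowest in adult testis (1.81), with 2.91 to 3.14 on the others. The mean deposited signal of 9 hybridization controls was 745 in adult testis and 1031 in neonatal ovary, against 1462 to 1675 on the others.

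In fetal gonads, 7 of 11 synaptonemal complex and axis genes were higher in ovary, and 5 of 10 Leydig, 7 of 19 Sertoli and 5 of 13 pluripotency genes were higher in testis. In all, 35 genes were 4-fold or more higher in fetal ovary than in fetal testis and 80 were lower. Smc1b, a meiosis-specific cohesin subunit, had a signal of 1962 in ovary and 96.7 in testis, a ratio of 20.3. Stra8, which is required for entry into meiosis, was 10.8-fold higher and Syce3, a protein of the synaptonemal complex, 8.38-fold higher. Terb1 and Spdya, which act at the attachment of meiotic telomeres to the nuclear envelope, and Meioc, which sustains meiotic prophase, were at the floor in testis and at least 9.97-fold, 8.48-fold and 8.93-fold higher in ovary. M1ap was at least 12.4-fold and Akr1c14 at least 6.05-fold higher, and Inca1, Irx3 and Ugt8a had ratios of 11.3, 9.21 and 8.67.

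Of the fixed gene lists, that of the synaptonemal complex and chromosome axis had 7 of 11 measured genes 4-fold or more higher in fetal ovary, with a median log2 ratio of 2.46, above 10000 random lists matched on mean signal. Among meiotic cohesins, 2 of 3 were higher (Smc1b and Rec8; median 2.16), and among genes of telomere attachment 3 of 5 (median 2.27). The recombination list had 2 of 18 genes higher, Dmc1 at 5.22-fold and Ccnb1ip1 at least 4.33-fold, with a median of 0.95. The list of meiotic entry had 2 of 5 higher, Stra8 and Meioc (median 0.69). None of the 24 measured genes for meiosis I segregation and the kinetochore differed by 4-fold, and their median was -0.23. Bub1, a spindle checkpoint kinase, had signals of 1923 in ovary and 1487 in testis, and Sgo2a, which protects centromeric cohesion, had 474 and 589.

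The genes lower in fetal ovary were led by Cyp17a1 and Cyp11a1, enzymes of steroid synthesis, which were at the floor in ovary and at least 125-fold and 67.4-fold lower than in testis. Hsd3b1 was 14.2-fold lower. The Leydig cell list had 5 of 10 genes lower and a median of -2.52, and the list of corpus luteum and theca, which shares Cyp17a1, Cyp11a1, Hsd3b1 and Star with it, had 5 of 9 lower (median -2.18). Sertoli cell genes were lower for 7 of 19, with a median of -0.99. Amh, the hormone that removes the female ducts in male fetuses, was at least 27.8-fold lower and Cst9, a cystatin, at least 53.4-fold lower. Defb19, Cbln1, Tesc and Tmem184a were lower by 32.8-fold, at least 29.7-fold, at least 22.2-fold and 9.27-fold, and AU015836 by 9.73-fold. Pluripotency genes were lower for 5 of 13 (median -1.33, or 0 with the floor at the 75th percentile), with Dppa4 at 23.3-fold and Utf1 at 9.84-fold. Genes of the fetal male germ cell and its piRNA pathway, which silences transposons, were lower for 4 of 9 (median -1.71). Dnmt3l, a cofactor of DNA methylation, was at the floor in ovary with 518 in testis. Granulosa cell genes, several of which Sertoli cells share, went both ways, with Fst and Irx3 higher and Amh, Inha and Hsd17b1 lower. The robust SD of 1 log2 ratio from pairs of probe sets was 0.16, which covers no variation between animals. A floor at the 25th or the 75th percentile gave 65 or 5 genes higher and 144 or 22 lower.

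In adult testis against neonatal testis, all late spermatocyte and spermatid genes that were above the floor on at least 1 array were higher. Most genes of the extracellular matrix and most imprinted growth genes were lower. The counts were 1939 genes higher and 1876 lower. All 24 measured spermatid genes were 4-fold or more higher, with a median log2 ratio of 6.31. So were the 12 late spermatocyte genes above the floor on at least 1 array (median 5.80), and both medians lay above the random lists. H1f6, also on the late spermatocyte list, was at the floor on all arrays and was left out. Prm2 and Tnp1, which replace histones in spermatid chromatin, had signals of 12070 and 10201 in adult testis and were at the floor in neonatal testis, ratios of at least 160 and 135. Meig1, Fabp9, Oaz3 and Spata4 were at least 140-fold, 138-fold, 136-fold and 135-fold higher. Ldhc, the lactate dehydrogenase of germ cells, was 91.1-fold higher and Odf2, a protein of the sperm tail, 88.4-fold higher. Spaca9, Cabyr, Actl7b and Fam71e1 had ratios of 84.1, 73.9, 73.4 and 72.1.

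Among meiotic prophase genes, those 4-fold or more higher in adult testis were 3 of 3 cohesins (median 4.04), 7 of 11 synaptonemal complex and axis genes (median 3.08), 3 of 5 telomere attachment genes (median 2.36) and 6 of 18 recombination genes (median 0.83), the last 2 medians inside the central 95% of random lists. Stag3 rounded out the cohesins with signals of 3860 in adult and 288 in neonatal testis. Spo11, the enzyme that makes meiotic DNA breaks, had 1903 against 80.4. Of the recombination genes only Mnd1 was 4-fold or more lower. In the list for meiosis I segregation and the kinetochore, 2 of 24 genes were higher and 3 lower, with a median of 0.07. The higher ones were Meikin, a protector of centromeric cohesion in meiosis I, which had a signal of 492 and was at the floor on the other 5 arrays, and Aurkc, a kinase of meiotic cells, with 808 against the floor. The lower ones were Cenpa, the histone of centromeres (104 against 2082), Mad2l1, a spindle checkpoint protein (430 against 1757), and Fbxo5. Mitotic cohesins had 4 of 9 lower (Smc1a, Rad21, Stag2 and Pds5b; median -1.82), but another probe set of Rad21 had a log2 ratio of 1.26 and another of Stag2 of 1.02. General germ cell genes had 2 of 10 higher, Mael and Tex101 (median 1.63).

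Lower in adult testis were 13 of 14 extracellular matrix genes (median -3.67), 8 of 10 imprinted growth genes (median -4.59), 7 of 14 proliferation genes (median -2.02), 7 of 10 Leydig genes (median -2.49), 7 of 19 Sertoli genes (median -1.46) and 5 of 8 smooth muscle genes (median -2.08). Dlk1, an imprinted regulator of fetal growth, had a signal of 10297 in neonatal testis and was at the floor in adult testis, at least 137-fold lower. Mfap4 and Col5a2, genes of the extracellular matrix, were at least 74.3-fold and 61.0-fold lower, Mmp2 48.7-fold and Islr 51.9-fold lower. Amh and Cbln1 were at least 70.5-fold and 85.7-fold lower. Itm2a, Pdlim4, Ppic and Septin11 were lower by 98.3-fold, 56.0-fold, 49.6-fold and 48.4-fold. Igfbp5 was at least 54.3-fold lower by the probe set used, while its other probe set had signals of 89.3 in neonatal and 176 in adult testis. Endothelial genes were lower for 3 of 10 (median -1.78) and granulosa genes, several of which Sertoli cells share, for 8 of 19 (median -0.97). Housekeeping genes had a median of -1.33 and macrophage genes of -1.03, neither outside the central 95% of random lists, and these were 0.04 and 0.30 when arrays were scaled to the hybridization controls. Under that scaling the median log2 ratio of genes above the floor on both arrays went from -0.50 to 0.90, and 3809 genes were higher and 460 lower. The SD of 1 log2 ratio from pairs of probe sets was 0.57 here. Of the 3732 genes with such pairs, 13.1% had probe sets that differed by more than 4-fold.

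The overlap of the 2 comparisons gave the genes that were higher in fetal ovary than in fetal testis and in adult than in neonatal testis. The first ratio also spans the sexes, and the second spans age and the presence of spermatids. Membership alone therefore does not tie a gene to meiosis. Of the 35 genes higher in fetal ovary, 18 were also 4-fold or more higher in adult testis than in neonatal testis, against 3.73 for independent lists of these sizes among 18193 genes. Genes at the floor on all arrays are counted among the 18193 but cannot be called. The 3.73, and such numbers below, are therefore too low. The 2 ratios share no array. In order of the smaller ratio, with ratios to the floor taken at their lower bound, the 18 genes were Smc1b, M1ap, Terb1, Meioc, Spdya, Syce3, Sycp3, Sycp1, Hormad1, Inca1, Syce1, Meiob, 1700013H16Rik, Majin, Fmr1nb, Rec8, Ccnb1ip1 and Lypd4. Of these, 13 stand on the fixed meiotic lists, as genes of cohesin, of the synaptonemal complex and axis, of telomere attachment, of meiotic entry or of recombination. The other 5 were M1ap, Inca1, 1700013H16Rik, Fmr1nb and Lypd4. Smc1b was 20.3-fold higher in fetal ovary and 16.5-fold higher in adult testis. M1ap was at least 12.4-fold and at least 14.4-fold higher, Inca1 11.3-fold and 5.85-fold, and Fmr1nb 8.20-fold and 4.58-fold. Lypd4 lay close to the limit in fetal ovary (303 against the floor, at least 4.02-fold) and was at least 90.0-fold higher in adult testis. In adult ovary 15 of the 18 were at the floor, and all 18 were 4-fold or more lower there than in fetal ovary. For the 15 this fall follows from the selection, because each member had at least 4 times the floor in fetal ovary. In neonatal ovary 8 of the 18 were at the floor, whereas Sycp3 kept a signal of 3051 against 3715 in fetal ovary and Syce1 953 against 1255.

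Among the 17 genes higher in fetal ovary and not in the overlap were Stra8, with 1.42-fold between adult and neonatal testis, Dmc1 with 1.92-fold, and Atf7ip2, with 3.99-fold. Granulosa genes (Fst, Irx3), Figla and Xist were in this part too. Each scaling gave between 18 and 20 overlap genes, though quantile normalization exchanged Lypd4 for Atf7ip2 and the hybridization controls exchanged Ccnb1ip1 and Lypd4 for 4930447C04Rik and Dmc1, and fetal testis in place of neonatal testis gave 18, which then shares an array between the 2 ratios. A ratio of 2 or more gave 75 genes against 37.3 for independent lists and a ratio of 8 or more gave 6 against 0.926, and a floor at the 25th or 75th percentile gave 34 or 2.

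**Figure D1:**
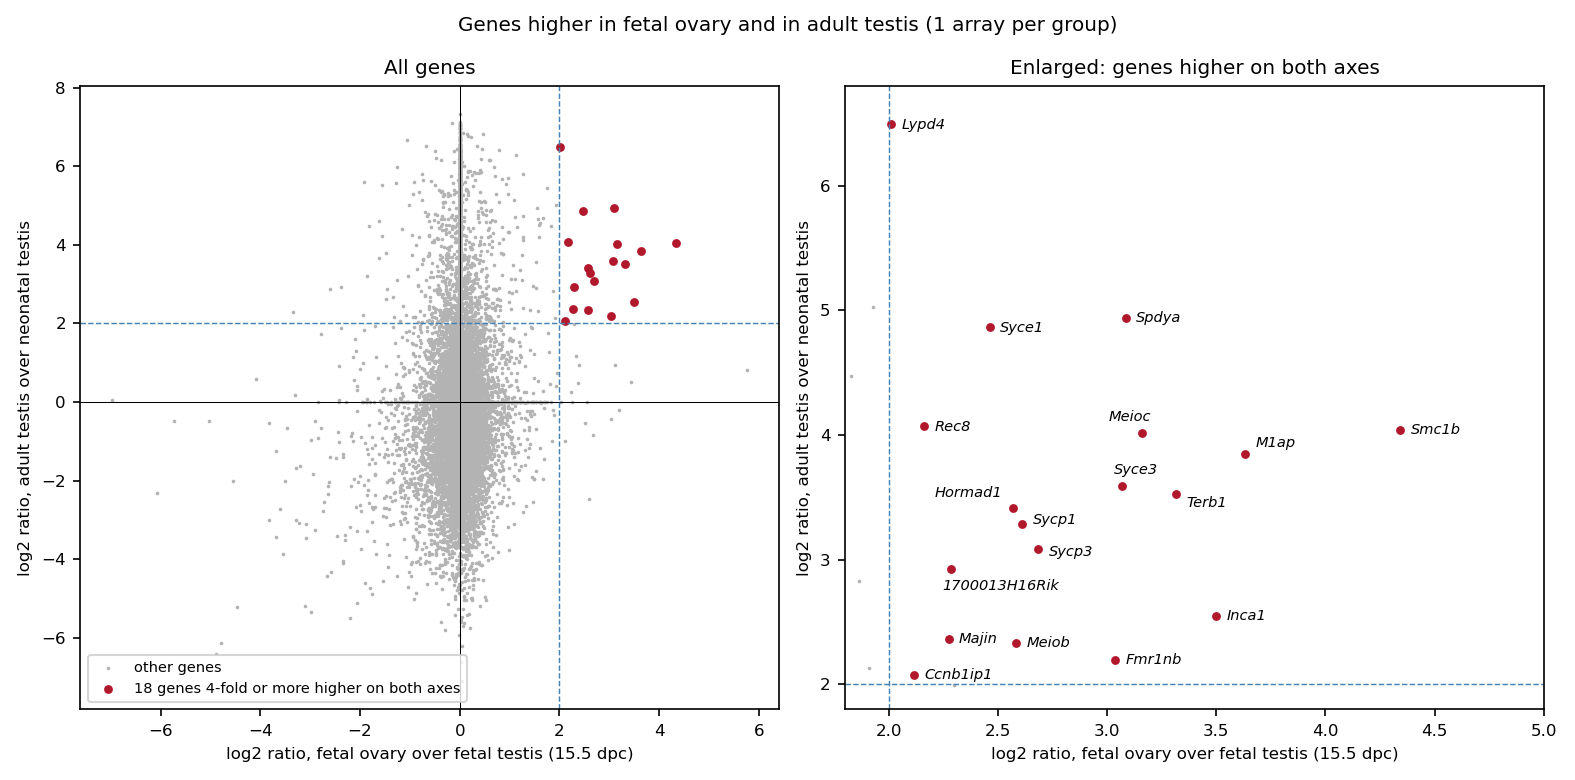
Log2 ratio of fetal ovary over fetal testis (horizontal) against log2 ratio of adult testis over neonatal testis (vertical), 1 point per gene, with all genes on the left and the upper right corner enlarged on the right. Dashed lines mark a ratio of 4, and the 18 genes above both are red, with Smc1b farthest to the right at 20.3-fold and Lypd4 at the top at 90.0-fold or more, a lower bound because neonatal testis is at the floor.

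**Figure D2:**
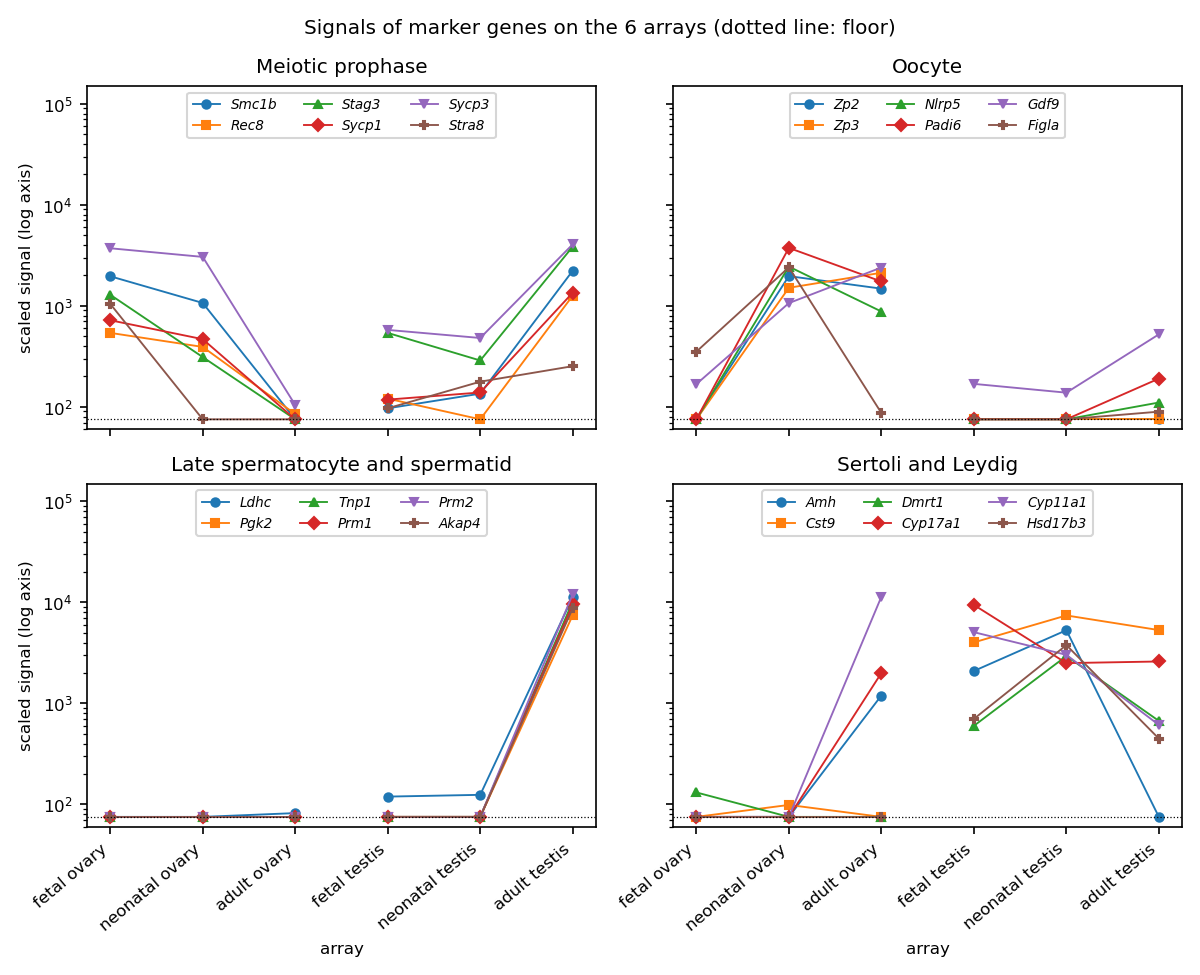
Scaled signal (log axis) of 24 marker genes on the 6 arrays, in 4 panels by gene group, with lines joining the ages within each sex and a dotted line at the floor of 75.3. Meiotic prophase genes such as Sycp3 are high in fetal ovary (3715) and adult testis (4067), the oocyte genes are high in neonatal ovary and, except Figla (2405 in neonatal, 87.0 in adult ovary), in adult ovary, and spermatid genes such as Prm2 are above the floor in adult testis (12070) and not on the other arrays.

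In neonatal gonads, 11 of 21 oocyte genes were higher in ovary, and 11 of 19 Sertoli and 5 of 10 Leydig genes were higher in testis. There were 254 genes higher in neonatal ovary than in neonatal testis and 175 lower. The oocyte list had a median log2 ratio of 2.95, above the random lists. Dppa3, Padi6, Nlrp5, Figla and Zp2, genes of the egg, its maternal stores and its coat, were at the floor in testis and at least 65.2-fold, 49.8-fold, 32.5-fold, 31.9-fold and 26.1-fold higher in ovary. The list of mesonephros, duct and oviduct epithelium had 8 of 11 genes higher (median 2.64). Ovgp1, a glycoprotein secreted by the oviduct, was 25.9-fold higher, and the keratin genes Krt8 and Krt18 had signals of 4565 and 4779 in ovary against 692 and 531 in testis, and of 1860 and 1928 in fetal testis. Bzw2 had the highest ratio above the floor, 113, from a probe set with a signal of 13269 in neonatal ovary, whereas a further probe set of Bzw2 had 381 in ovary and 538 in testis. Moxd1, Xist, Xdh, Tnfrsf19 and Plet1 were higher by 44.4-fold, 24.7-fold, 23.8-fold, 23.6-fold and at least 29.9-fold. Meiotic cohesins had 2 of 3 genes higher (median 2.38), while synaptonemal complex genes had 2 of 11 (Sycp3 and Syce1) and a median of 0.00.

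Sertoli genes were lower in neonatal ovary for 11 of 19 (median -2.63, below the random lists), with Cst9 at 75.1-fold, Dhh, a ligand of Sertoli cells, at 30.7-fold and Amh at least 70.5-fold. Defb19, Bcan, Gsta2 and Acsbg1 were lower by 68.8-fold, 30.1-fold, 24.3-fold and 22.4-fold, and Cbln1 and Mmd2 by at least 85.7-fold and 66.5-fold. Leydig genes were lower for 5 of 10 (median -1.83), with Cyp11a1 at least 40.2-fold lower. Hsd17b3, which makes testosterone and stands on both the Leydig and the Sertoli list, was at least 50.2-fold lower. Hsd17b1 was at least 40.3-fold lower. Granulosa genes, several of which Sertoli cells share, again went both ways, 3 higher (Foxl2, Rspo1 and Irx3) and 7 lower. Spermatogonial genes had a median of -1.11, with Dmrt1 lower and Kit higher in ovary. The macrophage list had no gene past 4-fold and a median of 0.95, and the endothelial list had none and a median of 0.55. The neonatal ovary array had the highest 3' to 5' ratio for Gapdh (3.12) but not for Actb (3.28, against 3.78 in fetal ovary). With signals as deposited 178 genes were higher and 206 lower, and with the hybridization controls 368 and 101.

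In adult gonads, all spermatid and late spermatocyte genes that were above the floor on at least 1 array were lower in ovary. Most genes of granulosa cells, the corpus luteum and theca, oocytes and the extracellular matrix were higher. There were 2166 genes higher in adult ovary than in adult testis and 1980 lower. All 24 spermatid genes (median -6.31) and the 12 late spermatocyte genes without H1f6 (median -5.84) were lower in ovary. Prm2 was at least 160-fold and Ldhc 138-fold lower. Odf2, St6galnac2, Ropn1l, Spata33 and Tcp11 were lower by 108-fold, 98.5-fold, 98.3-fold, 88.1-fold and 87.1-fold. Lower too were meiotic cohesins (3 of 3, median -4.89), synaptonemal complex and axis genes (9 of 11, median -4.10), telomere attachment genes (3 of 5, median -2.36), recombination genes (6 of 18, median -1.31), meiotic entry genes (2 of 5, median -1.75) and general germ cell genes (7 of 10, median -3.94), by the counts in brackets, with the medians for telomere attachment and entry inside the central 95% of random lists. With the floor at the 75th percentile the recombination and entry medians were 0. For meiosis I segregation and the kinetochore 2 of 24 were higher, Cenpa and Fbxo5, and 4 lower, Meikin, Bub1, Ttk and Espl1 (median -0.71).

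Luteal and theca genes were higher in adult ovary for 7 of 9 (median 3.61), granulosa genes for 14 of 19 (median 3.38), oocyte genes for 13 of 21 (median 2.20), macrophage genes for 6 of 10 (median 2.76) and extracellular matrix genes for 11 of 14 (median 3.17), each above the random lists. Leydig genes, several of them shared with theca cells, were higher for 6 of 10 (median 2.18), endothelial genes for 5 of 10 (median 1.97) and smooth muscle genes for 4 of 8 (median 2.05). Housekeeping genes moved too, with Pgk1, Gusb, Hprt and B2m higher by 8.91-fold, 8.32-fold, 6.12-fold and 4.63-fold and Tbp 5.22-fold lower. A rise in ovary was thus not confined to the cell type lists. Nr5a2, a nuclear receptor of granulosa cells, and Akr1c18, which inactivates progesterone, were at the floor in testis and at least 64.9-fold and 58.7-fold higher in ovary. Sfrp4, a secreted inhibitor of Wnt signals, was 75.1-fold higher. Akr1c14, Nupr1, Fosl2 and Cnmd were at least 62.3-fold, 61.2-fold, 59.5-fold and 58.8-fold higher, and Ephx2, Prkar2b, Htra1, Sgk1 and Ppic had ratios of 91.0, 73.1, 58.8, about 50 and 47.0. Sertoli genes had 6 of 19 lower in ovary and 1 higher, Amh (median -0.12). With the hybridization controls the median log2 ratio of genes above the floor on both arrays went from 0.54 to -0.51, and 839 genes were higher and 3320 lower. The SD of 1 log2 ratio from pairs of probe sets was 0.63. Of the 3713 genes with such pairs, 15.2% had probe sets that differed by more than 4-fold. The adult testis array had a 3' to 5' ratio of 2.36 for Gapdh, above 4 other arrays, and of 1.81 for Actb, the lowest.

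Between fetal and neonatal ovary, 13 of 21 oocyte genes were higher at the later age, and part of the meiotic prophase genes were lower. There were 138 genes higher in neonatal ovary and 42 lower. The oocyte list had a median of 3.09, above the random lists, with Padi6, Nlrp5 and Zp2 at the floor in fetal ovary and at least 49.8-fold, 32.5-fold and 26.1-fold higher. Nlrp4f, which is not on that list, was at the floor in fetal ovary and at least 21.9-fold higher. Dppa3 was 19.4-fold and Gtsf1 16.3-fold higher. AU015836, Fndc1 and Mfap5 had ratios of 14.9, 14.5 and 11.2. The bright probe set of Bzw2 had a ratio of 77.0, while the further one went the other way (806 in fetal, 381 in neonatal ovary). Ovgp1 and Xdh had ratios of at least 26.0 and 25.4. Synaptonemal complex and axis genes were lower for 6 of 11 (median -2.05), telomere attachment genes for 2 of 5 (median -1.33), entry genes for 2 of 5 (median -1.10) and recombination genes for 2 of 18 (median -0.45). Of the meiotic cohesins only Stag3 passed 4-fold (1287 in fetal, 311 in neonatal ovary), with Smc1b 1.84-fold and Rec8 1.38-fold lower (median -0.88). Stra8, M1ap, 4930447C04Rik and Ugt8a were at the floor in neonatal ovary and at least 13.9-fold, 12.4-fold, 11.9-fold and 9.58-fold lower. Tex101, Tex12 and Atf7ip2 were lower by 14.6-fold, 6.96-fold and 6.51-fold, and Ppp1r3c and Hmga2 by 9.41-fold and 6.74-fold. Blood genes were lower for 3 of 4 (median -3.43), with the embryonic globins Hbb-y and Hba-x at least 97.3-fold and 16.4-fold and Slc4a1, an anion exchanger of red cells, 7.14-fold lower. Smooth muscle genes were higher for 3 of 8 (median 1.32) and the duct and oviduct list for 1 of 11 (median 0.72). With signals as deposited 76 genes were higher and 99 lower.

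Between neonatal and adult ovary, most luteal, theca and granulosa genes were higher in the adult, and most general germ cell and duct epithelium genes were lower. There were 270 genes higher and 343 lower. Luteal and theca genes were higher for 8 of 9 (median 3.71), granulosa genes for 11 of 19 (median 2.12) and Leydig genes for 6 of 10 (median 2.65). Cyp11a1, Hsd17b1 and Ptgfr, a prostaglandin receptor of the corpus luteum, were at the floor in neonatal ovary and at least 151-fold, 54.8-fold and 30.0-fold higher in adult ovary. Mgarp, Nap1l5 and Apoa4 were at least 92.3-fold, 49.6-fold and 28.8-fold higher. Cnmd, Acsbg1, Hao2, Inhba, Star and Abcb1b had ratios of 47.1, 35.6, 35.1, 28.5, 26.9 and 26.1. Lower in the adult were 6 of 10 general germ cell genes (median -2.71), 3 of 3 meiotic cohesins (median -2.21), 4 of 11 synaptonemal complex genes (median -1.10), 7 of 11 duct and oviduct genes (median -2.15) and 5 of 10 imprinted growth genes (median -2.67). Dlk1, Igf2, Sycp3 and Figla were lower by 74.7-fold, 38.2-fold, 29.2-fold and 27.6-fold, and Agtr2 and Plet1 by 30.7-fold and 28.9-fold. Nefm, Moxd1, Afp, Ecrg4, Fndc1 and Wfdc2 were at least 75.1-fold, 56.3-fold, 37.3-fold, 31.1-fold, 31.1-fold and 27.0-fold lower. Oocyte genes were mixed, with 2 of 21 higher (Zar1 and Oosp1), 3 lower (Figla, Nobox and Lhx8) and a median of 0.21. With signals as deposited 402 genes were higher and 194 lower.

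Between fetal and neonatal testis, 5 of 19 Sertoli genes were higher and 4 of 13 pluripotency genes lower at the later age. There were 65 genes higher and 80 lower. With scaling to the same median 85 were higher and 64 lower, and with the hybridization controls 40 and 92. The Sertoli list had a median of 1.13, above the random lists, with Cst12, a cystatin, at 18.5-fold and Hsd17b3 and Dmrt1 among them. Tmem114, Serpina5, Elovl2, Islr2 and 4930550L24Rik had ratios of 11.0, 10.4, 10.4, 10.4 and 11.4, and Egr2, Tmem242, S100b, Akr1c14, Qpct and Glb1l3 were at the floor in fetal testis and at least 5.03-fold higher. Spermatogonial genes had a median of 0.82, with Dmrt1 as the 1 gene past 4-fold. The pluripotency list had a median of -1.14, below the random lists, which was 0 with the floor at the 75th percentile, and fetal male germ cell genes were lower for 3 of 9 (median -1.05). Dppa3 was at the floor in neonatal testis and at least 24.2-fold lower. Duct and oviduct genes were lower for 2 of 11 (median -1.27), with Cdh16, a cadherin of kidney and duct epithelium, at least 7.74-fold lower. Blood genes were lower for 3 of 4 (median -3.20), with Hbb-y at least 73.0-fold, Hba-x at least 10.8-fold and Slc4a1 7.86-fold. Moxd1, Hmga2, Npy, Ppp1r3c and Igfbp2 were lower by 14.0-fold, 12.3-fold, 12.2-fold, 8.87-fold and 7.73-fold, and Rspo3 and Hoxa5 by at least 14.0-fold and 11.6-fold.

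**Figure D3:**
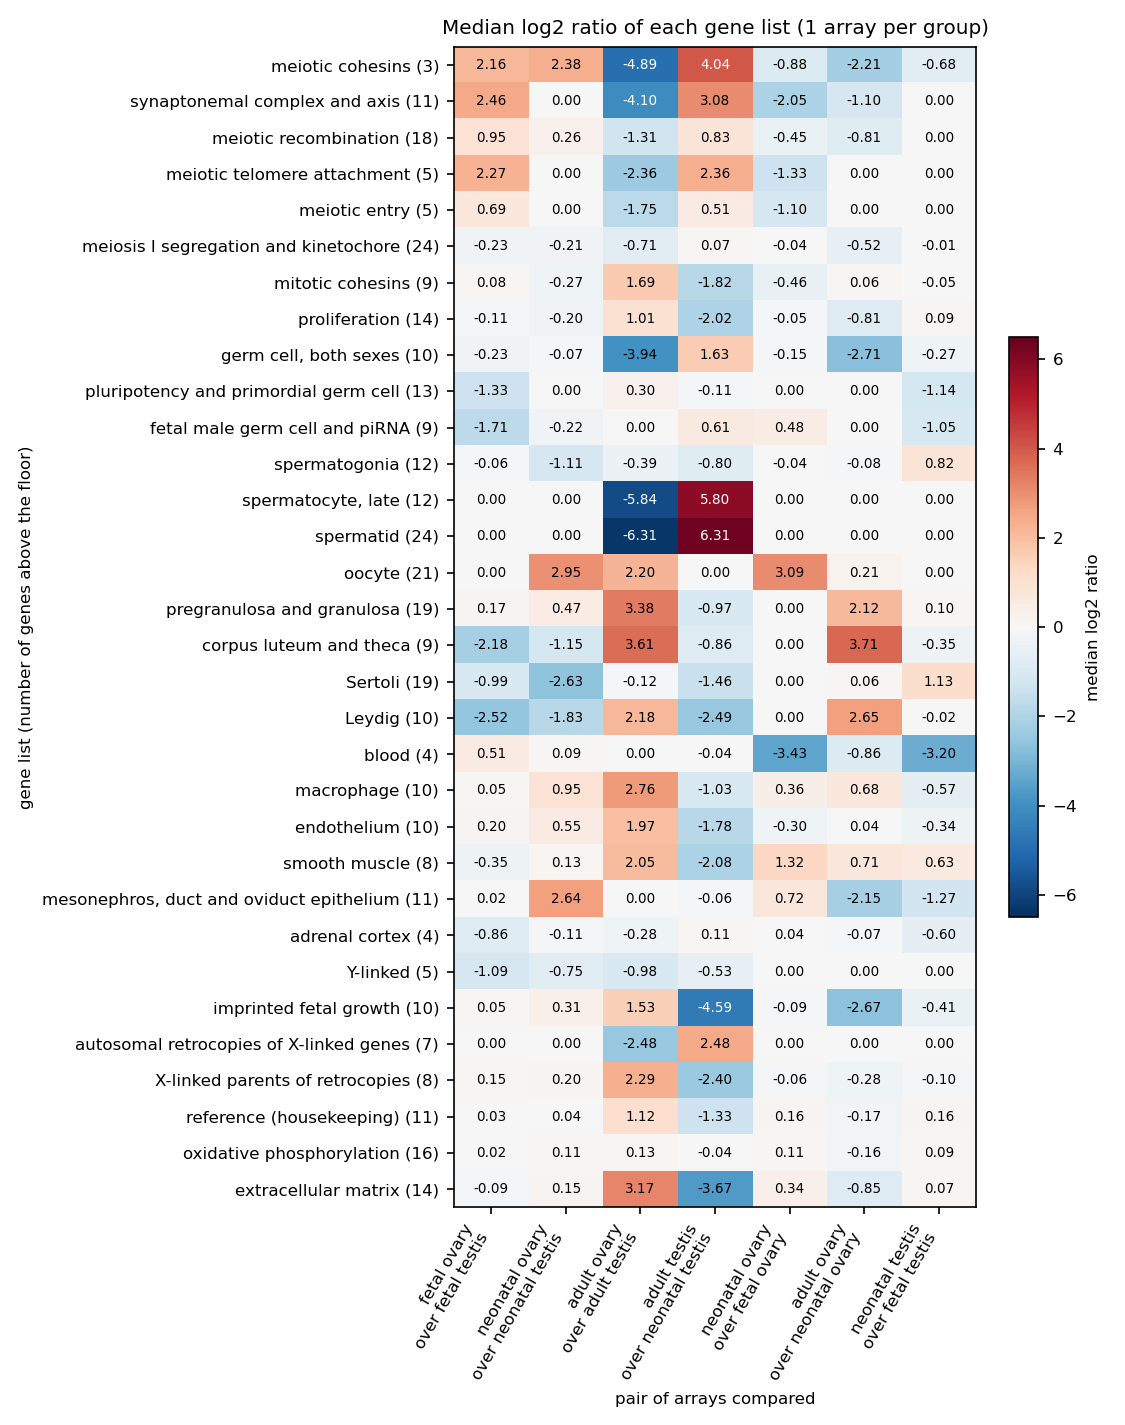
Median log2 ratio of each of the 32 fixed gene lists (vertical, with the number of genes above the floor on at least 1 array) in each of the 7 pairs of arrays (horizontal), as colour and as a printed value. Meiotic cohesins are at 2.16 in fetal ovary over fetal testis and at -4.89 in adult ovary over adult testis, and spermatid genes are at 6.31 in adult over neonatal testis. Under scaling to the hybridization controls the housekeeping and macrophage lists, at -1.33 and -1.03 in adult over neonatal testis, change sign.

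X-linked genes were lower in adult testis relative to autosomal genes. Among 528 genes of the X chromosome, the median log2 ratio of adult over neonatal testis was -1.12, below the random lists matched on mean signal, whose central 95% lay between -0.27 and 0, and the autosomal median was -0.13. A ratio of 4 or more downward was reached by 154 X-linked genes, or 29.2%, against 11.7% of the other genes, and upward by 50, or 9.47%, against 12.8%. The 19 autosomes had medians between -0.32 (chromosome 18) and -0.04 (chromosome 7). Genes of the X chromosome with higher signals in adult testis included Akap4, a scaffold of the sperm tail, at 8775 against the floor. Of 8 measured X-linked genes with an autosomal retrocopy, 5 were 4-fold or more lower in adult testis (median -2.40) and 5 of 7 retrocopies were higher (median 2.48, inside the central 95% of random lists). Pgk1, an enzyme of glycolysis, had signals of 6449 in neonatal and 784 in adult testis, and its autosomal copy Pgk2 was at the floor and at 7477. Pdha1 had 1454 and 179, and Pdha2 the floor and 4721. The probe sets of Cstf2, another of the X-linked genes, disagreed, with log2 ratios of -2.34 and 2.20. In the 5 comparisons without the adult testis the X-linked median was 0. In adult ovary over adult testis it was 1.06. The difference between the X-linked and the autosomal median, -0.99, was -0.87 with the hybridization controls, where the X-linked median was 0.00 and 5.49% of X-linked against 2.94% of autosomal genes were 4-fold or more lower, and -0.65 with the mean of all probe sets, where 15.9% of X-linked genes were 4-fold or more lower. With the floor at the 75th percentile both medians were 0, and 14.0% of X-linked against 4.54% of autosomal genes were lower.

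**Figure D4:**
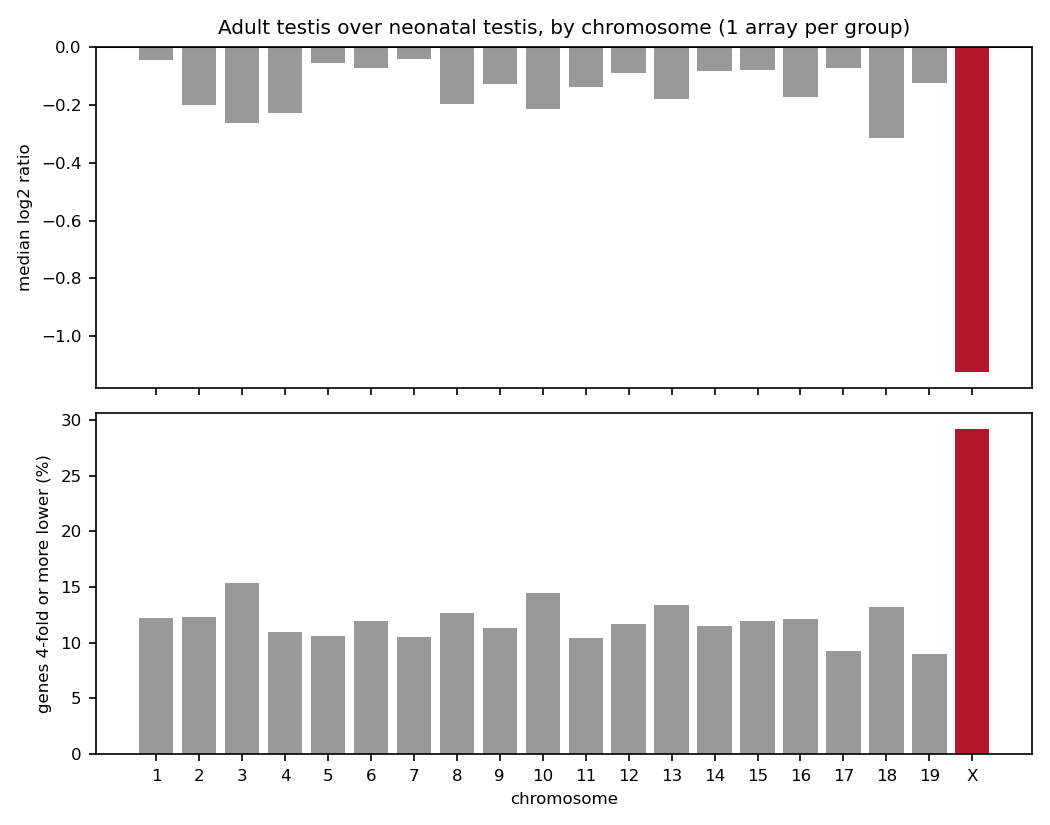
Median log2 ratio of adult over neonatal testis (top) and percentage of genes 4-fold or more lower in adult testis (bottom) for each chromosome, with 1 bar per chromosome and the X chromosome in red. The X chromosome stands at -1.12 and 29.2%, and chromosome 18, the lowest autosome by median, stands at -0.32.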

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

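Both patterns weighed below were picked after the data were seen. The somatic-cell test on X-linked genes and the test on a second epithelial list were set before their own values were seen. The scaling test on X-linked genes uses the numbers that showed the pattern. The test on oocyte expression was chosen, and its criterion later tightened, after its values were seen. The opposite directions between ages listed next were not tested, since each group has 1 array.

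Some gene lists were higher in ovary than in testis at an early age and lower at the adult age. Meiotic cohesins had a median log2 ratio of 2.38 in neonatal and -4.89 in adult gonads, synaptonemal complex and axis genes 2.46 in fetal and -4.10 in adult gonads, and telomere attachment genes 2.27 in fetal and -2.36 in adult gonads. The opposite order was seen for corpus luteum and theca genes, with -2.18 in fetal and 3.61 in adult gonads, and for Leydig genes, with -2.52 and 2.18. The medians 2.38, -4.89, -4.10, 2.27, -2.36 and -2.52 rest on a gene at the floor on 1 array, so their size is a lower bound. Of single genes, 20 were 4-fold higher in fetal ovary than in fetal testis and 4-fold lower in adult ovary than in adult testis, among them Smc1b, Sycp3 and Taf7l, and 19 went the other way, among them Cyp11a1, Hsd3b1, Amh and Inha. Between neonatal and adult gonads, 22 genes were higher in ovary first and lower later, among them Cfap54, Kif9 and Iqca, and 39 went the other way. Genes named in this paragraph were chosen after their values were seen.

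The first pattern weighed is the lower signal of X-linked genes in adult testis than in neonatal testis, a median log2 ratio of -1.12 over 528 genes (0 with the floor at the 75th percentile and 0.00 with the hybridization controls, so the direction against neonatal testis depends on floor and scaling). A scaling factor of the arrays moves X-linked and autosomal genes alike, and the X-linked median differed by -0.987 from the middle of the expression-matched random lists. That argues against such a factor as the whole cause, but the value restates the pattern and is no separate test. A lower share of somatic cells in the adult was tested on genes whose signals on the other 5 arrays were above 4 times the floor and within a factor of 2. Among these, 158 X-linked genes had a median of -2.29, a difference of -1.42 from the middle of matched lists. Of them 64.6% were 4-fold or more lower, against 17.1% of the other genes. X-linked genes thus fell further than other genes of even signal. The test cannot exclude a lower somatic share, because an even signal on 5 arrays does not show equal expression in germ and somatic cells. What stays open is a lower transcription of the X chromosome in male germ cells in and after meiosis. It may account for the pattern but was not itself tested here. A lower somatic share and other differences between the neonatal and the adult age stay open too, and the design cannot separate them.

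The second pattern is the higher signal of duct and oviduct epithelium genes in neonatal ovary than in neonatal testis (8 of 11 genes 4-fold or more), part of which lies in the testis, since Cdh16 had 583 in fetal testis and was at the floor in neonatal testis, Krt18 had 1928 and 531 and Emx2 856 and 148, and against fetal ovary only 1 of 11, Ovgp1, was 4-fold or more higher. Epithelium of duct or oviduct carried along at dissection may be a source, and of a second list of 21 measured epithelial genes 9 (42.9%) were 2-fold or more higher than in both neonatal testis and fetal ovary, against 3.34% of all genes above the floor in neonatal ovary, a share between the limits set for and against it. Among these 9 were Upk3b, Krt19 and Krt7, which the surface epithelium of the ovary also expresses. Their log2 ratios over fetal ovary were 1.02, 1.15 and 1.08, close to the 2-fold limit, and Ap1m2 missed it with 0.998. The median log2 ratio of neonatal over fetal ovary went from -0.02 to -0.48 with signals as deposited and to 0.21 with the hybridization controls. The share of 42.9% therefore depends on the scaling and was not computed under the other scalings. For expression in oocytes, the 8 duct genes kept a median of 0.196 of their neonatal signal in adult ovary, against 0.751 for the oocyte genes that were higher in neonatal ovary. As first written, the criterion compared these medians and was met, which spoke against oocytes; it was then tightened, with the values known, to ask that no such oocyte gene keep under 0.25 of its signal, and since 3 of 11 did, the tightened form cannot tell.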

How the results depend on the processing

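Scaling to the hybridization controls was chosen after the data were seen, and the other alternatives before. No paired analysis was possible because each comparison reported here has 1 array per group. A sex effect averaged over the 3 ages, with age as a block, asks a different question and was left out. With 1 array per group no comparison could be run without a doubted array. Neither ratio behind the overlap of 18 genes is taken on the neonatal ovary array. That array still enters the common floor, the scaling target and the choice of probe set. The floor limits what can be called, since a gene at the floor on 1 array needs 4 times the floor on the other. Of 168 results for the leading genes of each comparison and direction (overlap and list members not counted), all kept their direction under 8 of the alternatives. Without the probe sets that can cross-hybridize 165 of 166 did, and Igfbp5, for adult over neonatal testis, had a log2 ratio of 0.98 because a different probe set is then used. Still 4-fold or more were 129 of the 168 with the floor at the 75th percentile, 151 with the mean of all probe sets, 164 with the hybridization controls and all 168 under quantile normalization, signals as deposited, the same median, the floor at the 25th percentile and 16 added. Of 74 list medians of 1 or more in size, 72 kept their direction with the hybridization controls, 65 with the floor at the 75th percentile, and all 74 otherwise. The other 9 under that floor were 0: pluripotency (fetal gonads and neonatal over fetal testis), Y-linked (fetal), luteum and theca and spermatogonia (neonatal gonads), entry and recombination (adult gonads), macrophage (adult over neonatal testis) and synaptonemal complex (adult over neonatal ovary). Fewer stayed at 1 or more in size: 41 with the floor at the 75th percentile, 58 with the hybridization controls, 61 with the mean of all probe sets and 69 to 74 otherwise. Quantile normalization, scaling to the same median, omission of cross-hybridizing probe sets and the fetal testis as reference moved no count by over 1.5 times. The cause of the changes in the counts below was not tested beyond the construction of each alternative.

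Main counts, higher and lower, were 35 and 80 for fetal ovary over fetal testis, 254 and 175 for neonatal ovary over neonatal testis, 2166 and 1980 for adult ovary over adult testis, 1939 and 1876 for adult over neonatal testis, 138 and 42 for neonatal over fetal ovary, 270 and 343 for adult over neonatal ovary, and 65 and 80 for neonatal over fetal testis. In the same order of comparisons, the floor at the 25th percentile gave 65 and 144, 467 higher, 289 and 83 (neonatal over fetal ovary), 622 lower (adult over neonatal ovary), 101 and 175 (testis), and an overlap of 34. The floor at the 75th percentile gave 5 and 22, 72 and 72, 787 and 1196, 1172 and 741, 36 and 4, 100 and 93, 22 and 13, and an overlap of 2. With 16 added and no floor there were 388 higher in neonatal ovary over testis, 226 higher in neonatal over fetal ovary, 516 lower in adult over neonatal ovary and 128 lower in neonatal over fetal testis. The mean of all probe sets gave 160 higher in neonatal ovary over testis, 1177 higher in adult ovary over testis, 1060 lower in adult over neonatal testis, 225 lower in adult over neonatal ovary, and 43 and 51 in neonatal over fetal testis. Signals as deposited gave 76 and 99 in neonatal over fetal ovary and 194 lower in adult over neonatal ovary. The hybridization controls gave 101 lower in neonatal ovary over testis, 839 and 3320 in adult ovary over testis, 3809 and 460 in adult over neonatal testis, and 40 higher in neonatal over fetal testis. The overlap had 75 genes at a ratio of 2 and 6 at a ratio of 8.

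The share of called genes that were higher moved with the scaling. For neonatal ovary over testis it was 59.2%, against 46.4% as deposited, 48.7% at the same median and 78.5% with the hybridization controls. For neonatal over fetal ovary it was 76.7% and 43.4% as deposited, and for adult over neonatal ovary 44.0% and 67.4%. For neonatal over fetal testis it was 44.8%, against 34.3%, 57.0% at the same median and 30.3% with the hybridization controls. For adult ovary over testis it was 52.2% and 20.2% with the hybridization controls, and for adult over neonatal testis 50.8% and 89.2%.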

Other observations

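The groups below were read after the data were seen and have no test. Genes of oxidative phosphorylation were level in most comparisons, with medians of 0.02 in fetal ovary over fetal testis and -0.04 in adult over neonatal testis. The exceptions were subunits with forms in the testis. Cyct, the cytochrome c of the testis, had signals of 2884 in adult and 225 in neonatal testis, Cox6b2 7696 and 1522, and Cox8c 6146 and 477, while Cox6b1, the form of other tissues, had 1714 and 7648. Adrenal cortex genes were lower in fetal ovary than in fetal testis for 1 of 4 (median -0.86), Cyp11b1, which had 329 in fetal testis and was at the floor in all ovaries and in neonatal testis. Of 5 measured Y-linked genes only Eif2s3y was 4-fold or more lower in ovary at each age (medians -1.09 fetal, -0.75 neonatal and -0.98 adult). Imprinted growth genes were level between the sexes in fetal gonads (median 0.05). Uchl1, a ubiquitin hydrolase of germ cells and neurons, had 348 in fetal, 3219 in neonatal and 2211 in adult ovary.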
